A study of Mus musculus with 40 samples.

How the data were processed

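Colonic mucosa of mice was profiled by real-time quantitative PCR in 40 samples, 10 in each of 4 groups: germ-free, mono-associated with the Escherichia coli strain CEC for 21 days, mono-associated with the Escherichia coli strain Nissle for 21 days, and conventional. Group and replicate number were taken from the sample labels. Per the labels' protocols, total RNA was isolated with the mirVana kit and measured on a customized TaqMan OpenArray, a card of very small PCR wells that each hold 1 fluorescent probe assay. The design text deposited with the series says that RNA of the mice was pooled in equal amounts before the measurement, while 40 separate samples are given. The labels do not settle whether a sample is 1 mouse, so the p-values measure only the spread between these samples, which may be technical.

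The deposited table holds raw threshold cycles (Ct, in PCR cycles, where 1 cycle less is about a doubling of template) for 224 assays, 8960 values in all. Per the file headers the values are raw Ct, and the header calls the table a truncated example, so the panel may have held more assays. The threshold setting and the quality filters of the authors are not given in the sources used here. Assays are identified by TaqMan assay IDs alone. The files do not pair these IDs with genes, so assays are reported by ID. For the same reason the gene lists, the cell type markers and the reference genes fixed before the data were examined could not be matched to assays, and the planned gene list tests (camera and fry) and the planned reference-gene normalization were not run.

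Measured Ct ran from 13.06 to 36.67. A value of exactly 40 stood in 405 wells (4.52%) of 21 assays and was read as an undetermined well: 109 in germ-free, 111 in CEC, 93 in Nissle and 92 in conventional samples. Another 156 values (1.74%, in 51 assays) had been filled in before deposit: 153 equalled the mean of the other values of their group within 2e-06 cycles, and 3 equalled the mean of all but 1 of them. Filled-in values and undetermined wells were left missing. The handling of filled-in values was chosen after the table had been seen, and their use as deposited was added as an alternative. No sample repeated another. The closest pair (Nissle replicates 4 and 5) differed by a median absolute 0.275 log2 units, against a median of 0.746 between samples.

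Because no reference gene could be identified, the fallback named in the design was used: log2 relative expression is the sample's median Ct over the 153 assays measured in all 40 samples, minus the Ct of the assay. It assumes that the typical assay did not change and that each cycle doubles the product, so a shift shared by most of a chosen panel is removed with it. Means are given ± SD of these log2 values. In all, 6 comparisons were made: CEC, Nissle and conventional each against germ-free, CEC against Nissle, and each mono-associated group against conventional.

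Groups were compared with limma (version 3.58.1, in R 4.3.3; lmFit and eBayes) in 1 fit over all 4 groups with a contrast per comparison. An assay was tested where at least 5 of the 10 samples of both groups had a measured Ct. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The rule for named assays, also fixed beforehand, took up to 8 of the largest positive and negative changes past the threshold. As the IDs have no gene names, this was lowered after the file had been seen, and at most 2 higher and 2 lower assays are named per comparison. Detection was compared with Fisher's exact test on samples with and without a measured Ct. Overlap of the comparisons against the shared germ-free samples was set beside 100 simulations of unchanged groups and beside 100 splits of the germ-free samples into sets of 5. Principal components were computed on the 153 assays measured in all samples. Plots were drawn with matplotlib 3.10.9.

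The steps of the limma test were tested on simulated data. In 20 sets made for CEC against germ-free over 212 assays, with 16 assays shifted at each size, the test recovered 22.2% of assays shifted by 0.5 log2 units, 68.1% of those shifted by 1 and 91.6% of those shifted by 2, and 4.12% of its calls were false. The precision of a single assay is set by the 10 samples per group, and the median standard error of a log2 difference was 0.27 for CEC against germ-free. Other settings fixed before the data were examined were no normalization, undetermined wells at 1 cycle above the highest Ct (37.67), Ct above 30 as undetermined, a stricter and a looser filter on measured samples, fits with 2 groups only, sample quality weights (arrayWeights) and, where groups share replicate numbers, a replicate block. Settings added after the data had been seen were filled-in values as deposited, the mean Ct or the mean of the 10 most stable assays (geNorm) as the normalizer, each sample left out in turn, and Nissle replicates 4 and 5 left out together.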

Results

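Relative expression of 224 TaqMan assays was measured in the colonic mucosa of 40 mouse samples, 10 each from germ-free mice, mice mono-associated for 21 days with Escherichia coli CEC or with Escherichia coli Nissle, and conventional mice, which carry a full microbiota. Germ-free mice, which carry no microbes, were the control of the series. The sample median Ct depends on the amount of template and on the expression of the panel, which it cannot separate. It was 22.11 ± 0.351 cycles in germ-free (SD, n = 10), 22.34 ± 0.831 in CEC, 21.99 ± 0.457 in Nissle and 21.58 ± 0.342 in conventional samples. Between 6 and 15 of the 224 assays were undetermined in a sample. In 1 or more of the 6 comparisons, 105 assays changed.

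Conventional samples separated from the other 3 groups along the first principal component, which held 25.9% of the variance. Their scores averaged 8.01 ± 3.33 (SD, n = 10), with 3.17 as the lowest, against -1.15 ± 1.96 in germ-free, -1.88 ± 4.6 in CEC and -4.98 ± 3.83 in Nissle samples. The ranges still met, since CEC replicates 6 and 8 scored 8.28 and 4.53. CEC replicate 6 also lay at -27.36 on the second component, which held 17.3% of the variance, while the other 9 CEC samples lay between -3.54 and 1.35.

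**Figure D1:**
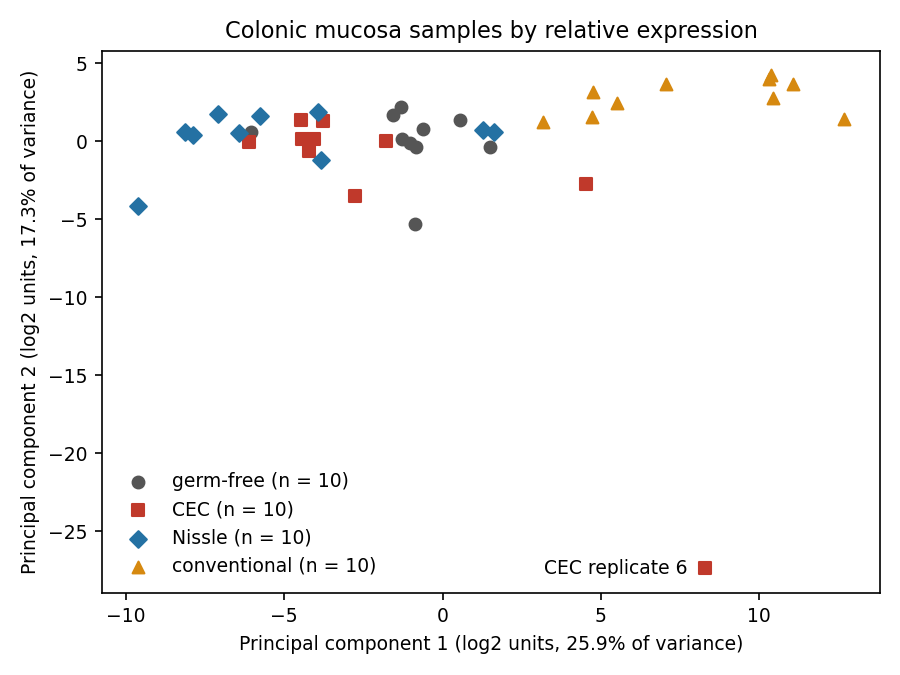
Scores of the 40 samples on the first 2 principal components of log2 relative expression, with 10 samples per group and each point 1 sample. Conventional samples lie to the right at 3.17 or more, and CEC replicate 6 lies alone at -27.36 on the vertical axis.

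The comparison of CEC with germ-free asks what 1 bacterial strain changes in the mucosa of mice without microbes. The assay with the largest rise was Mm00655850_m1, which was 161-fold higher after CEC: 1.24 ± 3.57 against -6.09 ± 3.87 log2 units (SD, n = 10 each), a difference of 7.33 with a standard error of 1.3 (limma, adjusted p = 8.21e-05). Its size rested on single samples and settings: it was 90.2-fold without CEC replicate 6, 79.9-fold without germ-free replicate 31, which lay at -15.23, 57.6-fold with Ct above 30 as undetermined and 62.2-fold with sample quality weights, and passed in each. Mm00470560_m1 was 8.18-fold higher, with -1.15 ± 2.05 against -4.18 ± 0.44, and every CEC sample lay above every germ-free sample (adjusted p = 0.000103). Mm00445845_m1 was 27.9-fold lower after CEC, with -2.85 ± 1.33 against 1.95 ± 1.33 (adjusted p = 8.21e-05), and Mm00472168_m1 was 5.4-fold lower, with 0.04 ± 1.07 against 2.47 ± 0.673 (adjusted p = 8.21e-05). For each of these 4 assays all 10 CEC samples lay on the same side of the germ-free mean. In total 19 of 213 tested assays changed, 9 higher and 10 lower, of which 6 rose and 6 fell by more than 2-fold. Group ranges did not overlap for 2 of the 19, which were themselves picked for small p-values in these samples. Without normalization 12 assays changed, 4 higher and 8 lower, while sample quality weights raised the count to 80 and leaving out CEC replicate 9 raised it to 29. Without CEC replicate 6, whose Mm00470560_m1 value of 4.58 stood far above the other CEC samples, 28 assays changed, 17 of them among the 19, and Mm00470560_m1 was 5.26-fold higher, near its 5.2-fold with sample quality weights (adjusted p = 7.1e-06, which ranged from 2.25e-07 to 0.00388 over its alternatives).

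The same assay, Mm00655850_m1, had the largest rise after Nissle, at 30.6-fold: -1.16 ± 2.34 against -6.09 ± 3.87 log2 units in germ-free (SD, n = 10 each), a difference of 4.93 with a standard error of 1.3 (limma, adjusted p = 0.013). It was 15.1-fold without germ-free replicate 31 (adjusted p = 0.0272). Mm01220132_g1 was 5.7-fold higher, with -5.42 ± 2.26 in 10 Nissle against -7.93 ± 1.09 in 8 germ-free samples (limma, adjusted p = 0.0295), and 3.64-fold higher without Nissle replicate 7, which lay at 0.41 (limma, adjusted p = 0.0361). Mm00445845_m1 was 19.2-fold lower, with -2.31 ± 3.01 against 1.95 ± 1.33 (adjusted p = 0.000577). It lay below the germ-free mean in 8 of 10 Nissle samples, while Nissle replicates 4 and 5, at 2.93 and 2.79, lay within the germ-free range, and it was 47.1-fold lower without these 2. Mm00484138_m1 was 5.03-fold lower, with -2.52 ± 0.893 against -0.19 ± 1.18, and lay below the germ-free mean in all 10 Nissle samples (adjusted p = 0.00481). In total 16 of 215 tested assays changed, 11 higher and 5 lower. Group ranges did not overlap for 2 of the 16. With the 10 most stable assays as the normalizer the 18 changed assays were 5 higher and 13 lower, 7 assays changed without normalization, 45 with sample quality weights, 25 without CEC replicate 6 and 25 without Nissle replicates 4 and 5. The call of Mm00655850_m1 ended when Ct above 30 counted as undetermined (10.9-fold, adjusted p = 0.0535, the highest of its alternatives, which reached down to 0.00209), and that of Mm01220132_g1 ended in a fit of the 2 groups alone (0.0596), with the 10 stable assays (0.0504) and without germ-free replicate 20 (0.0526), 22 (0.0626) or 32 (0.0522), while its lowest adjusted p over the alternatives was 0.0123.

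Conventional samples were set against germ-free samples to ask how mucosa with a full microbiota differs from mucosa without microbes. Mm00505670_m1 was 188-fold higher in conventional mucosa, with 2.45 ± 5.01 against -5.11 ± 0.912 log2 units (SD, n = 10 each), a difference of 7.56 with a standard error of 1.34 (limma, adjusted p = 8.84e-05). The rise was uneven: 7 conventional samples lay between 4.60 and 6.94, and the other 3, replicates 2, 3 and 4, between -6.44 and -3.39, close to the germ-free samples. The fold was 314 without replicate 2, 295 without replicate 3, 373 without replicate 4 and 90.1 with sample quality weights. Mm01288386_m1 was 21-fold higher, with -4.03 ± 4.04 in 10 conventional against -8.42 ± 0.645 in 5 germ-free samples (limma, adjusted p = 0.0272), and was undetermined in the other 5 germ-free samples. All 10 conventional samples lay above the 5 measured germ-free samples, whose highest was -7.71, with replicates 5, 7 and 8 at 0.17 to 2.77 and the other 7 between -7.55 and -5.44: the fold was 12.4 without replicate 7 and 243 with undetermined wells at 37.67 cycles, and the log2 difference fell from 4.39 to 3.72 without replicate 8. Mm01320260_m1 was 83.9-fold lower, with -8.71 ± 0.336 in 5 conventional against -2.31 ± 4.68 in 7 germ-free samples (limma, adjusted p = 0.0149); the other 5 conventional values had been filled in and were left out. Germ-free samples split into 4 at 0.94 to 1.86 and 3 at -7.92 to -6.07, and the fold was 51.8, 55.2 or 54 without germ-free replicate 21, 30 or 31, 129, 160 or 158 without replicate 10, 32 or 33, and 206 with sample quality weights. Mm00484138_m1 was 3.87-fold lower, with -2.15 ± 0.765 against -0.19 ± 1.18 (adjusted p = 0.0183), in 10 of 10 conventional samples. In total 39 of 214 tested assays changed, 14 higher and 25 lower. Ranges of the measured samples did not overlap for 6 of them. These include Mm01320260_m1, which was detected in only 7 of 10 germ-free samples. Its fold and its separate ranges leave out the undetermined germ-free wells, which stand for low or absent template. The balance of higher and lower calls turned with the normalizer: 31 assays changed with the 10 most stable assays, 24 higher and 7 lower, and 20 without normalization, 19 higher and 1 lower, against 25 assays with only those measured in all samples and 69 with sample quality weights. Leaving out germ-free replicate 20 left 19 changed assays and leaving out conventional replicate 9 left 23, while 47 changed without CEC replicate 6, including all 39. Mm01320260_m1 did not pass with undetermined wells at 37.67 cycles (5.46-fold lower, adjusted p = 0.525, against 2.52e-05 as the lowest of its alternatives), Mm01288386_m1 did not in a fit of the 2 groups (0.0781, lowest 0.000628) and Mm00484138_m1 did not without normalization (0.0548, lowest 0.000106).

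**Figure D2:**
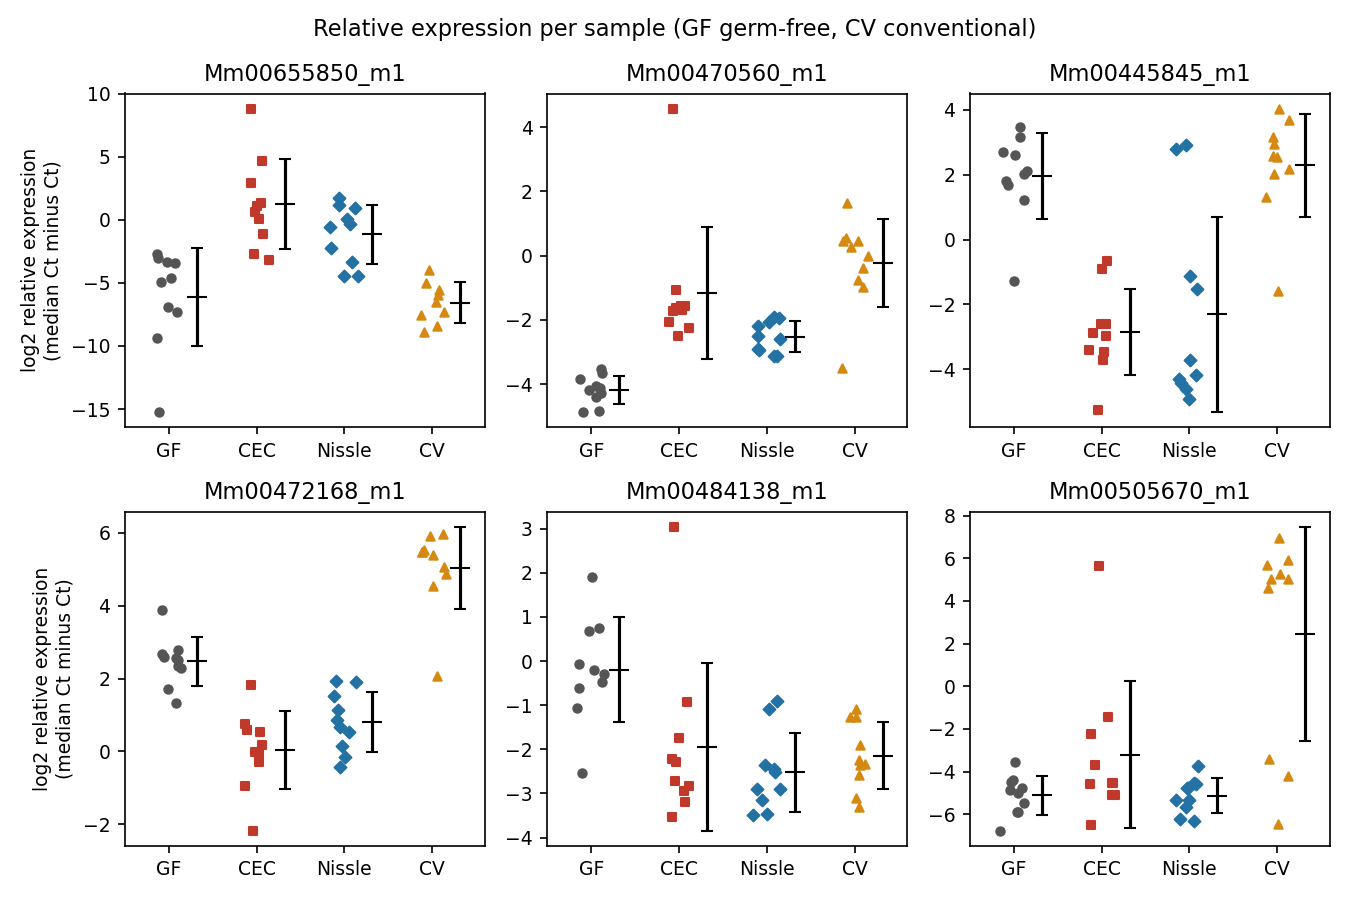
Log2 relative expression (sample median Ct minus assay Ct) of 6 named assays, with each point 1 sample and the bars the mean ± SD of a group (GF germ-free, CV conventional, at most 10 samples each). Mm00655850_m1 is high in both mono-associated groups, Mm00472168_m1 averages 5.03 in conventional samples and 0.04 in CEC samples, and Mm00505670_m1 lies between 4.60 and 6.94 in 7 conventional samples.

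Against germ-free, 4 assays changed in all 3 colonised groups. This set was picked out after the values had been seen. Mm00448160_m1 was higher in each, 6.96-fold after CEC (limma, adjusted p = 8.21e-05), 5.49-fold after Nissle (0.000577) and 4.93-fold in conventional samples (0.000807). Mm00484138_m1 and Mm00492427_m1 were lower in each, the latter by 1.65-fold, 1.55-fold and 1.47-fold, although its change in conventional samples did not pass with the 10 stable assays as the normalizer (adjusted p = 0.47). Mm00472168_m1 went in opposite directions. It fell from 2.47 ± 0.673 in germ-free (SD, n = 10) to 0.04 ± 1.07 after CEC and 0.81 ± 0.819 after Nissle (3.15-fold, adjusted p = 0.00709), and was at 5.03 ± 1.13 in conventional samples, 5.9-fold above germ-free (adjusted p = 2.8e-05). Mm00470560_m1 was also higher after CEC (8.18-fold), after Nissle (3.14-fold) and in conventional samples (15.5-fold), but did not pass after Nissle (limma, adjusted p = 0.0565). Every Nissle sample still lay above every germ-free sample for Mm00470560_m1. Without CEC replicate 6 it passed after Nissle (limma, adjusted p = 0.00104). Its log2 difference stayed at 1.651, while the standard error fell from 0.555 to 0.349. The fit shares 1 estimate of the spread over the 4 groups, so a CEC sample also enters this comparison.

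CEC and Nissle moved 8 assays past the threshold in the same direction, 4 higher and 4 lower, and none in opposite directions. Independent lists of these lengths would share 0.465 higher and 0.235 lower assays. In 100 simulations of unchanged groups against 1 common control, a median of 0 and at most 1 were shared. The simulations shuffled the samples' deviations from their group means, CEC replicate 6 included, so the simulated control mixed germ-free with colonised samples. With the germ-free samples split into separate sets of 5, a median of 4 assays were shared (0 to 7 over 100 splits). Across the 213 assays tested in both, which are not independent replicates, the log2 differences had a Pearson r of 0.666 (Spearman 0.511), against 0.502 in the simulations. Their covariance was 0.479 against 0.094 in the simulations, a difference of 0.385. The shared count was 4 without normalization and 29 with sample quality weights, and without CEC replicate 6 it was 12 and r was 0.738. CEC and conventional shared 5 assays in direction (2 higher, 3 lower) and had 2 in opposite directions, beside 0.549 higher and 1.17 lower from independent lists, with an r of 0.252, below the 0.455 of the simulations, and a covariance of 0.235 against 0.0861. Nissle and conventional shared 4 (2 higher, 2 lower) and had 1 in opposite directions, beside 0.72 and 0.584, with an r of 0.208, below the 0.484 of the simulations, and a covariance of 0.176 against 0.0736. For these 2 pairs r and covariance thus point to different sides of the simulated values. For both of these pairs the simulated groups shared a median of 0 assays, and with separate germ-free samples the medians were 2 and 1.

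The direct comparison of the strains tests whether CEC and Nissle differ in the mucosa. Of 214 tested assays 5 changed, all lower after CEC. Mm04207460_m1 was 8.8-fold lower, with -5.88 ± 1.38 in 8 CEC against -2.74 ± 2.86 in 10 Nissle samples (limma, adjusted p = 0.0426), and 5.4-fold lower with sample quality weights (limma, adjusted p = 0.0484). Mm00549170_m1 was 2.43-fold lower, with -0.32 ± 1.19 against 0.96 ± 0.731 (SD, n = 10 each; adjusted p = 0.0379), and lay below the Nissle mean in all 10 CEC samples. For Mm00655850_m1 the difference between the strains was 2.40 with a standard error of 1.3 (adjusted p = 0.286). No group ranges were separate, and 38 assays had an unadjusted p under 0.05. The count was 0 in a fit of the 2 groups (27 assays at an unadjusted p under 0.05), 0 with the replicate block, 3 with the 10 stable assays as the normalizer and 16 with sample quality weights. It was 2 without CEC replicate 4 or 8, 3 without CEC replicate 6, 12 without CEC replicate 10, 8 without Nissle replicate 2, 2 without Nissle replicate 5 or 9, 3 without Nissle replicate 8 and 2 without Nissle replicates 4 and 5. Both named calls were fragile: Mm04207460_m1 did not pass in 22 of 51 alternatives and Mm00549170_m1 in 11 of 52. Both had an adjusted p of 0.19 in the fit of the 2 groups and of 0.227 with the replicate block (limma). The adjusted p was 0.0699 and 0.0542 with the 10 stable assays and 0.0523 and 0.0592 without CEC replicate 6. It was 0.0612 each without Nissle replicates 4 and 5, and the lowest values were 0.0034 and 0.0177. Mm04207460_m1 was also lost (adjusted p from 0.0502 to 0.115) without any 1 of germ-free replicate 10, CEC replicates 3, 4, 5, 8, 9 and 10, conventional replicates 3, 4, 7, 8, 9 and 10 and Nissle replicates 5, 7, 8 and 9. Mm00549170_m1 was also lost (from 0.0523 to 0.105) without CEC replicate 4 or 8 or Nissle replicate 5, 8, 9 or 10. The smallest adjusted p, 0.00272, belonged to 2 other assays with smaller changes, and these 2 of the 5 remained without CEC replicate 6, though like all 5 they did not pass in the fit of the 2 groups.

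Against conventional mucosa, each mono-associated group differed in more assays than against germ-free mucosa. The difference between these counts was not tested. The labels give 21 days of colonisation for the mono-associated groups and no time for conventional mice. Length of colonisation and kind of microbiota therefore cannot be told apart here. Mm00655850_m1 was 224-fold higher after CEC than in conventional samples (limma, adjusted p = 3.1e-05) and 42.4-fold higher after Nissle (0.00278), where conventional samples had -6.56 ± 1.61 (SD, 9 samples). After CEC it was 125-fold higher without CEC replicate 6, 130-fold without normalization, 76.5-fold with sample quality weights and 428-fold with undetermined wells at 37.67 cycles, which gave 81-fold after Nissle. Mm01320260_m1 was 73.7-fold higher after CEC (adjusted p = 0.00386) and 24.5-fold higher after Nissle (0.0246), against 5 measured conventional samples. After CEC it was 42.5-fold higher without CEC replicate 6, 41.1-fold without normalization and 22.5-fold with sample quality weights. Mm00505670_m1 was 50.2-fold lower after CEC (adjusted p = 0.00178) and 190-fold lower after Nissle (0.000114), and Mm00445845_m1, at 2.29 ± 1.58 in conventional samples, was 35.3-fold lower after CEC (1.59e-05) and 24.4-fold lower after Nissle (0.000148). For Mm00505670_m1 the fold after CEC was 99.3 without CEC replicate 8, 83.8, 78.8 or 99.6 without conventional replicate 2, 3 or 4 and 85.6 without normalization, and after Nissle 317, 298 or 376 without these conventional samples and 107 with sample quality weights. Mm00445845_m1 was 60.2-fold lower after CEC without normalization and 59.8-fold lower after Nissle without Nissle replicates 4 and 5. In total 56 of 214 assays changed for CEC, 40 higher and 16 lower, and 70 of 215 for Nissle, 54 higher and 16 lower. With the 10 most stable assays as the normalizer the balance turned, to 12 higher and 27 lower for CEC and 10 higher and 45 lower for Nissle. These 10 were picked for a small spread relative to each other, so they can shift together between groups. With the median normalizer they were 0.131 to 0.4998 log2 units higher after CEC than in conventional samples, apart from Mm00466286_m1 at -0.0155. Among them Mm04210162_g1 was itself called changed (limma, adjusted p = 0.0341). Without normalization it was 6 higher and 52 lower for CEC and 3 higher and 18 lower for Nissle, sample quality weights gave 111 changed assays for CEC, and without CEC replicate 6 the counts were 78 and 83. Mm01320260_m1 after Nissle did not pass without normalization (adjusted p = 0.0701), with the 10 stable assays (0.0674) or with undetermined wells at 37.67 cycles (0.138), and its lowest adjusted p over the alternatives was 0.000133.

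**Figure D3:**
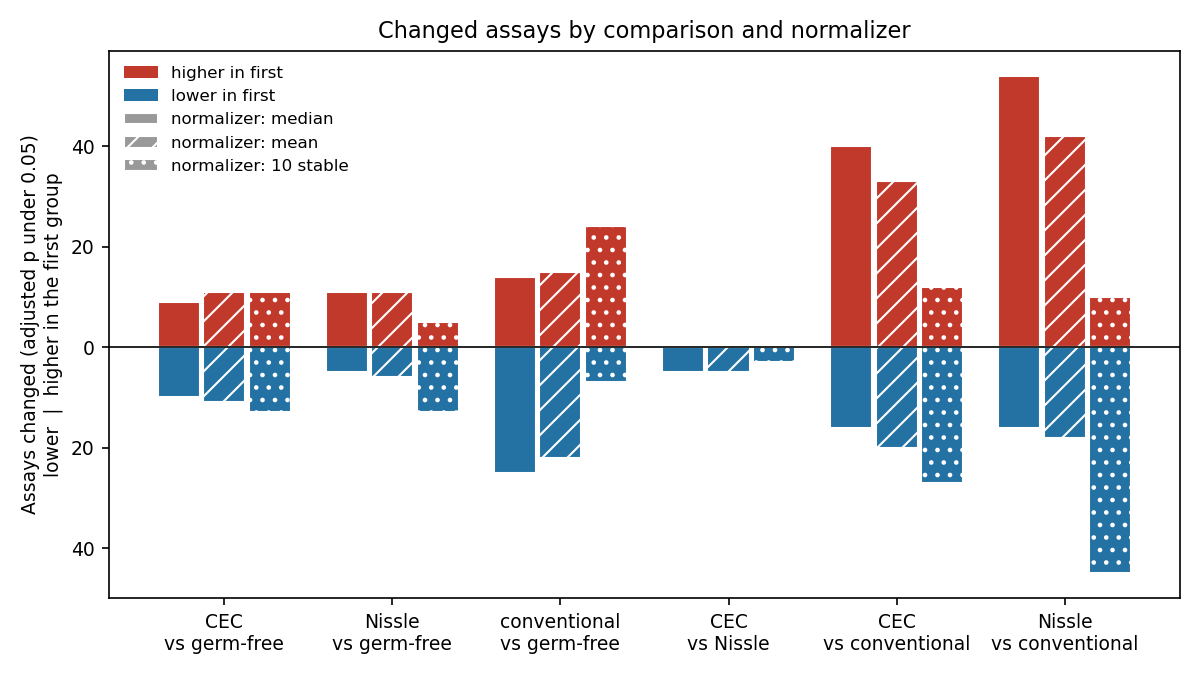
Number of assays past an adjusted p of 0.05 (limma) in the 6 comparisons, higher in the first-named group above 0 and lower in it below 0, with the median Ct, the mean Ct or the 10 most stable assays as the normalizer. For Nissle against conventional the median gives 54 higher and 16 lower assays and the 10 stable assays give 10 higher and 45 lower.

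Relative to the median normalizer, the 10 stable assays moved the median of all log2 differences by -0.207 for Nissle against germ-free, 0.284 for conventional against germ-free, 0.201 for CEC against Nissle, -0.289 for CEC against conventional and -0.49 for Nissle against conventional, and by -0.00548 for CEC against germ-free. Calls that passed in the same direction with the median, the mean and the 10 stable assays numbered 17 (8 higher, 9 lower) for CEC against germ-free, 9 (5 higher, 4 lower) for Nissle against germ-free, 20 (13 higher, 7 lower) for conventional against germ-free, 2 (0 higher, 2 lower) for CEC against Nissle, 28 (12 higher, 16 lower) for CEC against conventional and 26 (10 higher, 16 lower) for Nissle against conventional.

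Detection itself differed for no assay by Fisher's exact test after adjustment, over 15 assays for CEC, 17 for Nissle and 18 for conventional against germ-free and 15 for CEC against Nissle. Unadjusted p-values under 0.05 numbered 0, 0, 1 and 1. When Ct above 30 counted as undetermined, 1 assay passed, Mm01288386_m1, which was detected more often in conventional than in germ-free samples (Fisher's exact test, adjusted p = 0.0179).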

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

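The test of low RNA input for CEC replicate 6 was chosen only after the sample had been seen to stand apart, and it replaced a first version that could not tell. Samples far from the rest of their group were looked for in 60 sets of values, of which 15 held one. A chance rate of about 1 set in 20 would give about 3, but it presumes independent sets. These sets share samples and include the named assays, which were picked for large changes, so the excess over 3 does not measure chance. Among the 15, 4 were in CEC replicate 6. On the second principal component it lay at -27.36 (other CEC samples -3.54 to 1.35), for Mm00470560_m1 at 4.58 (others -2.51 to -1.06), for Mm00484138_m1 at 3.03 (others -3.54 to -0.92) and for Mm00549170_m1 at -3.27 (others -1.52 to 0.45).

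CEC replicate 6 deviated by more than 2 log2 units from its group median in 31 assays, against at most 8 in any other CEC sample. Low RNA input would raise every raw Ct, yet 14 assays had a raw Ct over 2 cycles below that of every other CEC sample. This argues against low input as the whole cause. The sample's median Ct of 23.45 was still high for the group, below only the 23.84 of CEC replicate 8. Replicate 8 had 6 such assays, so the test did not single out replicate 6, and low input as part of the cause stays open. CEC replicate 6 had a median distance to the samples of each other group of at least 1.25 times the largest such distance of any member of that group, which argues against a wrong label within this series as the whole cause. It lay as far outside the other CEC samples (1.24 against a largest 0.999), so a wrong label together with another cause stays open. A different tissue or cell composition of this sample, a sample from outside the series and a stronger response to CEC in this sample stay open and were not tested, since the assays could not be tied to cell type markers.

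Other samples lay far from their group on single measures. On the first principal component germ-free replicate 20 lay at -6.05 (other germ-free samples -1.58 to 1.49). On the second, germ-free replicate 12 lay at -5.33 (others -0.40 to 2.21) and Nissle replicate 1 at -4.13 (others -1.23 to 1.85). The median distance of Nissle replicate 8 to its own group was 1.06 log2 units (others 0.552 to 0.766). Germ-free replicate 31 had Mm00655850_m1 at -15.23 (others -9.35 to -2.74). Germ-free replicate 20 had Mm00445845_m1 at -1.27 (others 1.23 to 3.48), and conventional replicate 7 had it at -1.60 (others 1.31 to 4.04). Conventional replicate 5 had Mm00470560_m1 at -3.49 (others -0.98 to 1.65) and Mm00472168_m1 at 2.07 (others 4.54 to 5.98). Nissle replicate 7 had Mm01220132_g1 at 0.41 (others -7.34 to -4.38), and CEC replicate 8 had Mm00505670_m1 at 5.65 (others -6.50 to -1.42), within the range of the 7 high conventional samples.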

How the results depend on the processing

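Alternatives chosen only after the data had been seen were filled-in values as deposited, the 2 other normalizers, each sample left out and Nissle replicates 4 and 5 left out. Over settings fixed beforehand 41 counts stayed within 1.5 times their value and 16 did not; over added ones 293 did and 15 did not. Of 1097 alternative values of the named assays, 1052 kept direction and passed, 45 kept direction only and 0 reversed. Most of these alternatives left out 1 sample, also from groups outside the comparison, so many nearly repeat the main fit. A sample outside a comparison acts on it through the spread, which the fit shares over the 4 groups. Without CEC replicate 6 the median standard error for Nissle against germ-free fell from 0.27 to 0.249. Except where named, the cause of other changes was not tested. Without normalization the changed assays numbered 12 for CEC, 7 for Nissle and 20 for conventional against germ-free and 21 for Nissle against conventional, with 4 shared by CEC and Nissle. With only assays measured in all samples, 25 changed in conventional against germ-free, as fewer assays (153) were tested. A fit of the 2 groups gave 0 for CEC against Nissle (27 at an unadjusted p under 0.05). Sample quality weights gave 80, 45 and 69 against germ-free (CEC, Nissle, conventional), 16 for CEC against Nissle, 111 for CEC against conventional and 29 shared. The 10 stable assays gave 3 for CEC against Nissle. Germ-free samples split into sets of 5 gave 4 shared, with fewer samples per fit. Detection with Ct above 30 as undetermined gave 1 for conventional against germ-free. Without Nissle replicates 4 and 5, 25 changed for Nissle against germ-free and 2 for CEC against Nissle. Leaving out 1 sample gave 13 to 29 (CEC against germ-free, 29 without CEC replicate 9), 12 to 25 (Nissle against germ-free, 25 without CEC replicate 6), 19 to 47 (conventional against germ-free, 19 without germ-free replicate 20, 23 without conventional replicate 9), 2 to 12 (CEC against Nissle), 46 to 78 (CEC against conventional), 58 to 83 (Nissle against conventional) and 6 to 12 shared. The replicate block gave 0 for CEC against Nissle (23 at an unadjusted p under 0.05; both named assays at an adjusted p of 0.227), 58 for CEC and 52 for Nissle against conventional, where Mm00655850_m1 was 125-fold higher after CEC and Mm01320260_m1 43.1-fold after CEC and 42.6-fold after Nissle. By the criterion that every pair correlate above 0.1, numbers did not pair the samples: r between samples with the same number ran from -0.229 to 0.511, from -0.0953 to 0.445 and from -0.382 to 0.282 (CEC and Nissle, CEC and conventional, Nissle and conventional), 1, 7 and 3 of 10 pairs were above 0.1, and 1, 4 and 1 of 10 correlated best with their own number. The criterion is strict, so for CEC and conventional a link between samples of the same number stays open. No paired analysis was possible for germ-free comparisons because germ-free shares only number 10 with the other groups. Not run, because no assay could be tied to a gene: the mean of the reference genes, the 2 most stable reference genes and the gene list tests. The median normalizer, planned as an alternative, became the main setting. Undetermined wells limit 21 assays.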

Other observations

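The test of the normalizer was chosen only after the result had been seen. Some assays were at a high or a low level within 1 group, with little between. A gap of at least 4 log2 units with at least 2 samples on each side was found for 3 assays, 2 in conventional and 1 in germ-free samples. Mm00505670_m1 was at 4.60 to 6.94 in 7 conventional samples and at -6.44 to -3.39 in replicates 2, 3 and 4. Mm01288386_m1 was at 0.17 to 2.77 in conventional replicates 5, 7 and 8 and at -7.55 to -5.44 in the other 7. Mm01320260_m1 was at 0.94 to 1.86 in germ-free replicates 21, 22, 30 and 31, at -7.92 to -6.07 in replicates 10, 32 and 33, and undetermined in the remaining 3.

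Nissle replicates 4 and 5 were the closest pair of all samples, at 0.275 log2 units, and scored 1.29 and 1.62 on the first principal component, where the other 8 Nissle samples lay at -3.83 or below. Left out together, they raised the assays changed by Nissle from 16 to 25. That they were germ-free samples under the Nissle label was tested on those 25 assays: the pair lay on the Nissle side of the midpoint between the groups in 30% of cases (replicate 4 in 32%, replicate 5 in 28%), where germ-free samples did so in 0 to 28% and the other Nissle samples in 56 to 100%, ranges that come from the samples used to choose the assays. The share falls between the bounds set for the test, which leaves a wrong label open. Both lay over 1 log2 unit above every germ-free sample for Mm00655850_m1 (0.96 and 0.08), Mm00470560_m1 (-2.06 and -1.95) and Mm00448160_m1 (-3.61 and -2.96), but these 3 assays were picked for that, and single germ-free samples lay as far outside the others in 0 to 5 assays, so this does not settle it. As a hypothesis, the pair may have been colonised and shown only part of the response of the group, which was not tested.

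The balance of lower and higher calls in conventional against germ-free samples followed the normalizer. The lower calls made up 64.1% of 39 assays with the median and 22.6% of 31 with the 10 most stable assays, so the surplus of lower calls depends on the choice of normalizer. The change of normalizer moved the median log2 difference by 0.284 in all assays together, so the turn shows this dependence and not which balance is right. The median Ct exceeded the mean Ct of the 10 stable assays by 1.63 ± 0.234 cycles in conventional samples and by 1.91 ± 0.375 in germ-free samples (SD, n = 10 each). Which of the normalizers tracks the amount of RNA cannot be settled from these values, and a shift of most of the panel by the microbiota stays open and untested.

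Other splits of the 20 samples of a comparison into 10 and 10 were used to ask whether chance could give as many changed assays, with 100 splits each, the real one included. As many as the real split were reached by 1 split for CEC against germ-free (19 assays, highest other 13), 2 for Nissle against germ-free (16, highest other 30), 1 for conventional against germ-free (39, highest other 5), 3 for CEC against Nissle (5, highest other 7), 1 for CEC against conventional (56, highest other 10) and 1 for Nissle against conventional (70, highest other 14). These shares come from the fit over 4 groups, without adjustment for the 6 comparisons, and are under 0.05. With 100 splits no share can fall below 1 in 100. For the 4 comparisons that no other split reached, they argue against a chance split of these samples. Chance between mice is not excluded, since a sample may not be 1 mouse. For CEC against Nissle, 2 other splits reached the real count, a fit of the 2 groups alone called 0 assays (27 at an unadjusted p under 0.05, limma) and leaving out 1 sample gave 2 to 12, so chance stays open. The count of 16 alone leaves it open for Nissle against germ-free as well, where 1 other split gave 30 assays, more than the real groups. Of the 16 assays, 8 moved in the same direction after CEC, while simulated unchanged groups shared at most 1. Both comparisons use the same germ-free samples, and the simulated control mixed germ-free with colonised samples. With the germ-free samples split into separate sets, a median of 4 were shared (0 to 7). The overlap thus exceeded the simulations as a count, which does not exclude chance for any single assay of the 8.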
